A study of Danio rerio with 16 samples.

How the data were processed

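RNA came from pools of 50 dechorionated zebrafish embryos that were either homozygous for the nz171 allele of rad21a or wild type, collected at 24 or 48 hours post fertilisation (hpf). There were 4 pools per genotype and time, each a separate biological replicate per the labels and each hybridised to its own Affymetrix zebrafish genome array, which gave 16 arrays. RNA was extracted with Trizol, purified on columns and labelled with the single-cycle Affymetrix kit, per the labels' protocols. The deposited values are normalized probe set intensities on a linear scale, and GCOS, RMA and affy are the tools named in the submitters' processing notes. Versions of those tools, the background correction and any filter are not given in the sources used here. The median intensity per array lay between 45.9 and 48.4, and the table had 0 missing values. Values had been assumed to be on a log2 scale when the tests were laid out. They proved to be linear, so log2 was taken here without a pseudocount and the same tests were kept.

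The table held 15617 probe sets, of which 115 manufacturer controls were left out and 15502 were tested, with no filter on dim probe sets. Gene symbols came from the platform annotation: 10795 tested probe sets had 1 symbol, 135 had several and 4572 had none, and probe sets with several were not named. Symbols were brought up to date through the gene identifier with the RefSeq annotation of assembly GRCz12tu, in which 10711 of the probe sets with 1 symbol were found and 1 symbol changed. That annotation was used only for names and for which genes lie next to each other on a chromosome. The named probe sets stood for 8793 genes, of which 1539 had more than 1 probe set. A gene took its value from the probe set with the highest mean over the 16 arrays, and probe sets of a named gene that differed in direction or call are reported.

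Groups were compared with limma 3.58.1 in R 4.3.3. A model with a mean for each of the 4 groups was fitted to all 16 arrays, so that the groups shared a single estimate of the spread, with 12 residual degrees of freedom and an eBayes prior worth 4.97 more. The contrasts were mutant against wild type at each time, the difference between these contrasts (the interaction), and 48 against 24 hpf within each genotype. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg over the 15502 probe sets, and a probe set was called at an adjusted p under 0.05 with no minimum fold. The error after ± is the standard error (SE) of the fit for a log2 change and the standard deviation (SD) for a group mean, with n = 4 per group throughout. P-values of single genes below are limma adjusted p-values unless an exact test is named.

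There were 33 gene lists: cohesin subunits, cohesin loaders and regulators, p53 response, apoptosis machinery, Myc network, ribosome biogenesis, DNA replication, mitosis, DNA repair and checkpoint kinases, erythroid, blood stem and progenitor, myeloid, endothelium, neural progenitor, differentiated neuron, photoreceptor, lens, skeletal muscle, heart, neural crest and pigment, pharyngeal cartilage, somite clock and tailbud, notochord and hatching gland, epidermis, liver and yolk, pancreas and gut, hypoxia response, heat shock and stress, innate immune and interferon, ribosomal proteins, Hox genes, protocadherins and histones. Each list needed at least 5 measured genes. The lists were tested with camera (limma) at a preset correlation between genes of 0.01, on 1 probe set per gene, with adjustment over the 33 lists. Beside it stand camera with an estimated correlation and fry. The directional p of fry tests whether the genes of a list move, on balance, in the same direction, and its mixed p whether they change in either direction. Neither compares a list with other genes or lists. Members called are counted after adjustment over all probe sets and after adjustment over the list alone. Certain genes that were to be named whatever their values are not reported here.

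The genes named were set by rule. They were rad21a and every measured cohesin subunit; for mutant against wild type at each time, the 8 largest increases and 8 largest decreases among called genes with all 4 mutant arrays on 1 side of all 4 wild type arrays, which chance gives for 2.86% of genes; up to 4 members of each list by smallest adjusted p; myca, mdm2 and runx1 whatever their values; and the 6 largest changes in each direction for the interaction (without the condition on arrays) and the time comparisons. "Largest" refers to genes under this rule throughout. Names made of clone or locus identifiers were not eligible. A few genes outside this rule, named to complete a small count, were chosen after their values were seen. The comparisons, tests, lists, naming rule and alternatives of the report were fixed before the data were examined. Exceptions, added after the data were seen, are the alternative that leaves out together the 3 arrays least like their groups, each wild type array left out of the stage index, and those tests of explanations that the closing section names as chosen after the result was seen.

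A stage index placed each array on an axis from wild type at 24 hpf (0) to wild type at 48 hpf (1), built from probe sets called between these groups with a log2 change of at least 1 (705 to 885 probe sets). The axis was built 4 times, each time without 1 replicate number, so that no wild type array helped to build the axis it was placed on. Mutants and wild types were compared by exact two-sided permutation tests of 4 against 4 arrays, whose smallest possible p is 0.0286. A stage-matched wild type reference for the mutants at 48 hpf was set, on the log2 scale and in the same model, at the point between the wild type means that gives the mean index of those mutants (0.702 of the way from 24 to 48 hpf).

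The steps were tested on simulated data. With 100 probe sets of 15502 changed by a log2 of 0.5 and 100 by 1, the 24 hpf comparison recovered 49% and 92% of them, with 2.08% false calls among the calls. The 48 hpf comparison recovered 48% and 96%, with 7.10% false calls. In a comparison with no simulated change 0 calls were made. A simulated stage index of 0.7 was recovered as 0.687. The simulated mutants lay exactly on the wild type axis, so that this recovery tests the computation only. Simulated noise was independent between probe sets, whereas genes on the real arrays are correlated, so that the share of false calls there may differ. The number of arrays limits the precision of every value. Alternatives covered normalization (cyclic loess, median centring), a filter on the dimmest 25% of probe sets, a variance prior with a trend, array weights, other thresholds, the replicate number as a term, only the groups compared in the fit, each array left out in turn, and the 3 arrays least like their groups left out together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.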

Results

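Gene expression was measured in zebrafish embryos that lack a functional copy of rad21a, which encodes the kleisin subunit of cohesin, the ring-shaped complex that holds sister chromatids together and shapes chromatin loops. Dechorionated embryos homozygous for the nz171 allele were set against wild type embryos at 24 and 48 hpf, with 4 pools of 50 embryos per genotype and time and 1 array per pool. The first principal component of the 16 arrays held 50.65% of the variance and separated the times. The second component held 18.7%, with every wild type array above 0 and every mutant array below 0. Probe sets for 5 foreign sequences that embryos do not carry read between 2.77 and 7.22 in log2 intensity (median 4.66), so that values near or below this median lie close to background and fold changes against them are compressed.

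Signs of RNA quality and of single arrays differed as well. The log2 difference between the 3' and 5' control probe sets of the muscle actin acta1 was higher in mutants than in wild types by 0.616 at 24 hpf and 0.949 at 48 hpf (exact two-sided permutation p = 0.0286 each, the smallest possible, adjusted p = 0.0571 over 4 tests, higher in 4 of 4 mutant arrays). The same difference for GAPDH was 0.124 (exact permutation p = 0.143) and 0.0193 (exact permutation p = 0.514). Wild type replicate 1 at 24 hpf, wild type replicate 3 at 48 hpf and mutant replicate 4 at 48 hpf correlated least with their groups, with mean correlations of 0.985, 0.986 and 0.983.

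The targeted gene was low in every mutant array. The log2 intensity of rad21a was 10.09, 10.48, 10.55 and 10.40 in the wild type arrays at 24 hpf and 6.58, 6.72, 7.06 and 6.83 in the mutant arrays. At 48 hpf it was 10.48, 10.26, 10.06 and 10.15 in wild types and 6.57, 6.72, 6.05 and 5.92 in mutants. The mutant values lay within the upper part of the range of the foreign sequences, which came from a single sequence, pd2EGFP (group means 6.34 to 6.66). The other foreign sequences had group means of at most 5.38, below every mutant value of rad21a. The mutant levels of rad21a were 12-fold and 15.2-fold lower than in wild types (log2 change -3.58 ± 0.17, adjusted p = 4.94e-10, and -3.92 ± 0.17, adjusted p = 6.74e-11). The other 6 measured cohesin subunits were not called. At 24 hpf their log2 changes were 0.37 for stag1b, 0.09 for stag2b, 0.02 for both rad21l1 and stag2a, 0.00 for smc3 and -0.03 for smc1al. At 48 hpf they were 0.18 for stag2a, 0.08 for stag1b, 0.05 for rad21l1, -0.03 for stag2b, -0.31 for smc1al (adjusted p = 0.0679) and -0.38 for smc3 (adjusted p = 0.0824). A further probe set of smc1al read 0.15 at 48 hpf, and a further probe set of stag2b read -0.26 at 24 hpf, neither of them called. The main probe set of smc1al passed the threshold without wild type replicate 3 at 48 hpf (-0.41, adjusted p = 0.00928) and with arrays scaled by cyclic loess (-0.35, adjusted p = 0.0186) or centred (-0.34, adjusted p = 0.0474), and smc3 without mutant replicate 3 (-0.50, adjusted p = 0.0253). The cohesin subunit list as a whole, rad21a included, was not shifted by camera (adjusted p = 0.495 and 0.0884), and adjusted over the list alone rad21a was lower at 24 hpf and rad21a, smc1al and smc3 at 48 hpf. Its median (0.02) and mean (-0.45) differed in sign at 24 hpf.

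**Figure D1:**
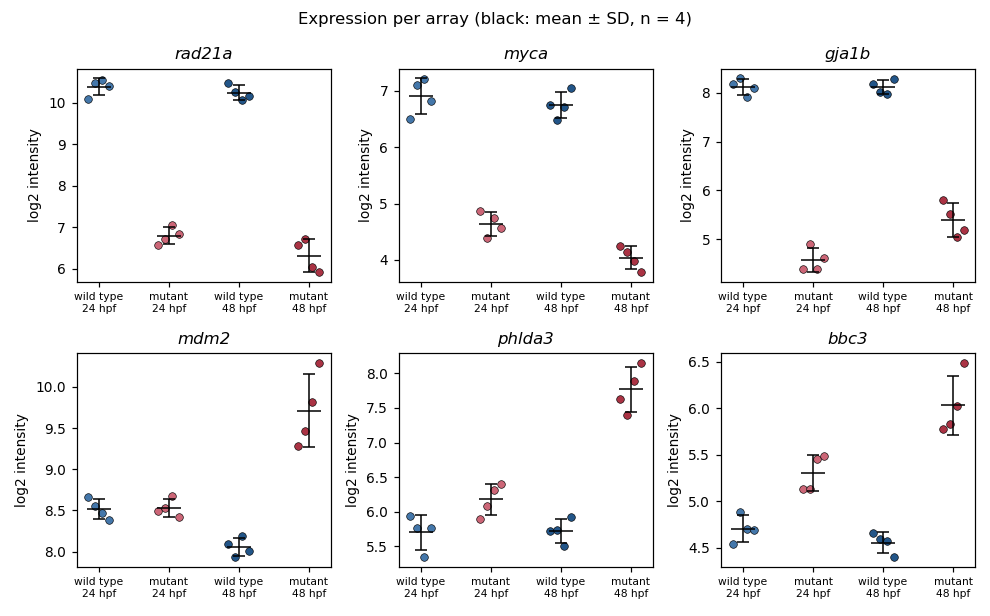
Log2 intensity of rad21a, myca, gja1b, mdm2, phlda3 and bbc3 on each array (points) with the group mean and SD (black, n = 4), by genotype and time. All mutant values of rad21a lie at or below 7.06 and all wild type values at or above 10.06, and mdm2 is higher in mutants at 48 hpf, with means of 9.71 against 8.06.

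The comparison at 24 hpf asked which transcripts differ between mutants and wild types after the first day of development. Among genes with a symbol, the largest falls beyond rad21a were in gja1b, a connexin of gap junctions, which was 11.8-fold lower (log2 change -3.56 ± 0.15, adjusted p = 2.42e-10), and inka1a, an inhibitor of p21-activated kinase, 9.19-fold lower (-3.20 ± 0.15, adjusted p = 7.07e-10). The growth regulator myca, a Myc transcription factor, was 4.83-fold lower (-2.27 ± 0.16, adjusted p = 2.17e-07). Its mutant mean of 4.64 lay at the median of the foreign sequences. The ribosome biogenesis and DNA replication lists shifted down by camera, but not with an estimated correlation (adjusted p = 0.249 and 0.266 with an estimated correlation). Some early blood, neural progenitor and heart genes fell as well. In all, 1139 of 15502 probe sets were called, 505 higher and 634 lower in mutants, of which 29 and 88 changed at least 2-fold.

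Further large decreases were in myhz1.3, a fast muscle myosin heavy chain (-2.16 ± 0.37), bhlhe22, a transcription factor of developing neurons (-2.12 ± 0.16), atp1a1a.2, a sodium pump subunit (-2.07 ± 0.23), and aqp1a.1, a water channel of red blood cells and vessels (-1.86 ± 0.24). The mutant means of bhlhe22 (3.60), gja1b (4.57) and inka1a (4.60) were below the median of the foreign sequences. Among genes with a symbol, the largest increases were in scamp5a, a membrane protein of synaptic vesicles, 4.33-fold higher (2.12 ± 0.41, adjusted p = 0.00391), and the ubiquitin-conjugating enzyme ube2d2, 3.78-fold higher (1.92 ± 0.16, adjusted p = 1.5e-06). They were followed by hnmt, which inactivates histamine (1.48 ± 0.23), cyp1a, a cytochrome P450 induced through the aryl hydrocarbon receptor (1.24 ± 0.28), the actin-capping gene capgb (1.23 ± 0.20), the collagen col28a2a (1.2 ± 0.21), the matrix-associated aebp1b (1.19 ± 0.27) and aldh18a1, an enzyme of proline synthesis (1.16 ± 0.16). The call of aebp1b ended when only the 24 hpf arrays entered the fit (adjusted p = 0.0548).

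In the Myc network list, 4 of 9 members fell, 1 rose and 4 did not pass (6 and 1 adjusted over the list alone). The members that fell were myca, mycb (-0.89), mycn (-0.74) and mych (-1.06), and the member that rose was mxd4 (0.85), which encodes a Myc antagonist. In ribosome biogenesis 29 of 51 fell and 22 did not pass (41 adjusted over the list alone). Among those that fell were fbl, which methylates ribosomal RNA (-0.78), rrp9 (-1.02), nop58 (-0.57) and the polymerase I subunit polr1b (-0.79, with another probe set at -0.20 that was not called). In DNA replication 17 of 41 fell and 24 did not pass (38 adjusted over the list alone). Log2 changes were -0.91 for the polymerase subunit pold2, -0.80 for the helicase subunit mcm5, -0.76 for slbp and -0.79 for fen1. The lists had camera adjusted p-values of 0.00204, 1.4e-22 and 4.38e-18. They were not called when the correlation between genes was estimated (adjusted p = 0.249, 0.249 and 0.266 with an estimated correlation, in the same order). By contrast with replication, 2 of 38 mitosis genes fell and 36 did not pass (2 adjusted over the list alone, camera adjusted p = 0.0593), the kinetochore gene spc24 (-0.62) and the cyclin ccnb2 (-0.51). In DNA repair and checkpoint kinases only the clamp gene rad1 fell of 18 (-0.45; 2 adjusted over the list alone), although the list shifted down by camera (adjusted p = 0.00118; adjusted p = 0.594 with an estimated correlation and 0.062 by fry).

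The p53 response list was not shifted at 24 hpf (camera adjusted p = 0.0619): 3 of 16 rose and 13 did not pass (5 adjusted over the list alone). The 3 were tp53inp1 (0.85), rps27l (0.86) and bbc3, which encodes the cell death inducer Puma (0.60). The value of mdm2, which encodes a ubiquitin ligase, was 0.01 ± 0.16 (adjusted p = 0.987). Of 16 apoptosis machinery genes, casp9 (0.72) and bik (0.54) rose, cycsb (-0.43) fell and 13 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.491, median -0.08 against a mean of 0.07). In the histone list hist2h2l rose (1.07, with another probe set at 0.23 that was not called) and 7 of 8 did not pass (3 adjusted over the list alone, camera adjusted p = 0.0619, fry adjusted p = 0.00448). None of 66 ribosomal protein genes passed, adjusted or at an unadjusted limma p under 0.05 (camera adjusted p = 0.822, median just below 0 against a mean of 0.01). The same held for the 16 innate immune and interferon genes, where 0 passed either way (camera adjusted p = 0.825).

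Among tissue lists, heart and pharyngeal cartilage shifted down by camera. In heart, 3 of 14 fell and 11 did not pass (3 adjusted over the list alone, camera adjusted p = 0.00439; adjusted p = 0.249 with an estimated correlation). The 3 were klf2a, a flow-responsive factor of endocardium (-1.02), the myosin heavy chain myh7 (-0.95) and has2, which makes hyaluronan (-0.54). In pharyngeal cartilage, 3 of 19 fell and 16 did not pass (6 adjusted over the list alone, camera adjusted p = 0.00842; adjusted p = 0.249 with an estimated correlation). These were the distal-less homeobox genes dlx2b (-0.65), dlx5a (-0.60) and dlx2a (-0.76). A permutation test of array means was added after the result was seen. There pharyngeal cartilage had an exact two-sided p of 0.143 (adjusted p = 0.277), and heart the smallest possible, 0.0286 (adjusted p = 0.0943). Blood genes that fell were cahz, the red cell carbonic anhydrase (-1.41), in the erythroid list (1 of 16; 1 adjusted over the list alone, camera adjusted p = 0.0619). So did myb (-0.87), cxcr4a (-0.46) and runx3 (-0.42, with another probe set at -0.08 that was not called) among 11 blood stem and progenitor genes, where meis1b rose (0.43; 4 and 1 adjusted over the list alone, camera adjusted p = 0.423). In the myeloid list lyz, the lysozyme of leukocytes (-1.29), and mmp13a (-1.05) fell of 15 (2 adjusted over the list alone, camera adjusted p = 0.155). The value of runx1, a regulator of blood stem cells, was 0.01 ± 0.13, at a level of 3.57, below the median of the foreign sequences. Of 8 endothelial genes 0 passed in limma, with 1 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.599).

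In the nervous system and lens, 3 of 20 neural progenitor genes fell, 1 rose and 16 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.0662). The proneural genes ascl1b (-1.56) and ascl1a (-1.79) and the glial lipid-binding gene fabp7a (-1.54) fell, and the Notch ligand dlb rose (0.48, with another probe set at 0.22 that was not called). Of 27 differentiated neuron genes, inab (-1.06) and isl2a (-0.55) fell and gap43 rose (0.57; 2 and 2 adjusted over the list alone, camera adjusted p = 0.474). Of 19 photoreceptor genes, nr2e3 fell (-0.34) and rcvrn2 rose (0.45, with another probe set at 0.03 that was not called; 1 and 1 adjusted over the list alone, camera adjusted p = 0.893, median -0.02 against a mean of 0.00). In the lens list 3 of 11 fell and 8 did not pass (3 adjusted over the list alone, camera adjusted p = 0.108), the crystallins cryba4 (-0.88) and crybb1 (-1.19) and the transcription factor prox1a (-0.52). The protocadherin pcdh10a fell (-1.72, with another probe set at -0.17 that was not called) of 7 protocadherins (2 adjusted over the list alone, camera adjusted p = 0.0537).

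The remaining lists were not shifted at 24 hpf. In skeletal muscle myod1 fell (-0.55) and tmod4 rose (0.47) of 33 (1 and 1 adjusted over the list alone, camera adjusted p = 0.0619), in arrays whose actin 3' to 5' difference was higher by 0.616. In neural crest and pigment, sox10 rose (0.51) and sox9b fell (-0.75, with another probe set at -0.07 that was not called) of 15 (1 and 1 adjusted over the list alone, camera adjusted p = 0.822). Of 13 somite clock and tailbud genes evx1 (-0.66) and fgf8a (-0.53) fell (4 adjusted over the list alone, camera adjusted p = 0.0627). Of 8 notochord and hatching gland genes cd63 rose (0.47) and cav1 fell (-0.46, with 2 other probe sets not called; 1 and 3 adjusted over the list alone, camera adjusted p = 0.45). Of 24 epidermis genes agr2 (-1.38) and icn (-0.85) fell and krt18a.1 rose (0.38; 2 and 2 adjusted over the list alone, camera adjusted p = 0.822, median 0.07 against a mean of -0.02). Of 24 liver and yolk genes 0 passed in limma, with 2 higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.634, median -0.01 against a mean of 0.03). Of 26 pancreas and gut genes foxa3 (-0.67) and ins, which encodes insulin (-0.50), fell (2 adjusted over the list alone, camera adjusted p = 0.219). Of 17 hypoxia response genes pfkfb4b rose (1.01) and vegfaa (-0.51) and igfbp1a (-1.48, with another probe set at -1.06 that was not called) fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.822). Of 28 heat shock and stress genes hspd1 (-0.61), asns (-0.60, with another probe set at -0.43 that was not called), atf4a (-0.44) and junbb (-1.65) fell (4 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.13). Of 6 cohesin loaders and regulators cdca5, which encodes sororin, rose (0.61; 1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.822), and the acetyltransferase esco2 read -0.64 (adjusted p = 0.07). The mean of that list was just below 0 and its median 0.08. Of 42 Hox genes hoxc9a rose (0.39; 1 adjusted over the list alone, camera adjusted p = 0.253).

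The count at 24 hpf moved with single arrays. It was 738 without wild type replicate 2, 662 without wild type replicate 3, 694 without mutant replicate 3 and 646 without mutant replicate 4. The 6 shifted lists became 11 without wild type replicate 1, 10 without mutant replicate 3 and 11 without mutant replicate 4, and 17 of the 35 splits of the 8 arrays gave at least 6 lists. Single calls with an adjusted p near the threshold also rested on single arrays. Without mutant replicate 4 the adjusted p was 0.056 for bbc3, 0.0569 for isl2a, 0.0561 for mmp13a, 0.0574 for prox1a, 0.0537 for evx1 and 0.05 for hspd1. Without wild type replicate 3 it was 0.0542 for isl2a, 0.0528 for mmp13a and 0.0597 for tmod4. Without wild type replicate 2 it was 0.0553 for prox1a and 0.056 for evx1, and without mutant replicate 3 it was 0.0539 for bbc3. The calls of asns, atf4a, bik, cav1, ccnb2, cdca5, cxcr4a, cycsb, dlb, dlx2a, fgf8a, gap43, hoxc9a, igfbp1a, junbb, krt18a.1, nr2e3, rad1, rcvrn2, sox10 and sox9b each ended without any of 3 to 8 arrays, at adjusted p-values from 0.0506 to 0.167.

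At 48 hpf the same question was put to embryos a day older. The erythroid, myeloid and lens lists were lower and the p53 response list was higher in mutants, and fin fold actinodins were among the largest falls. None of these 4 lists was called with an estimated correlation (adjusted p = 0.25, 0.309, 0.13 and 0.146 with an estimated correlation, in this order). The claudin cldn11a, a tight junction protein, was 14.6-fold lower (log2 change -3.86 ± 0.11, adjusted p = 2.8e-13), with a mutant mean of 3.60, below the median of the foreign sequences. The fin fold actinodins and2 and and3, fibre proteins of the fin rays' forerunners, were 11.5-fold and 7.06-fold lower (-3.53 ± 0.34, adjusted p = 2.17e-06, and -2.82 ± 0.19, adjusted p = 4.17e-08). The p53 target phlda3, an inhibitor of Akt signalling, was 4.12-fold higher (2.04 ± 0.16, adjusted p = 2.43e-07) and mdm2 3.15-fold higher (1.66 ± 0.16, adjusted p = 1.8e-06). In all, 2413 probe sets were called, 1358 higher and 1055 lower, of which 123 and 218 changed at least 2-fold.

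The decreases also included aqp1a.1 (-3.08 ± 0.24), cahz (-3.05 ± 0.26), inka1a (-2.91 ± 0.15), lyz (-2.80 ± 0.23) and myca (-2.71 ± 0.16), whose mutant mean was 4.04. Among genes with a symbol, the largest increases besides that of phlda3 were in s100b, a calcium-binding protein (2.29 ± 0.22, adjusted p = 1.6e-06), and hnmt (2.26 ± 0.23, adjusted p = 3.69e-06). They were followed by the zinc finger gene znf346 (2.11 ± 0.33), msmo1, an enzyme of sterol synthesis (1.98 ± 0.38), the endosomal plekhf1 (1.74 ± 0.27) and isg15, the interferon-induced ubiquitin-like protein (1.72 ± 0.53, adjusted p = 0.0344). The wild type means of s100b (3.55), hnmt (3.88), msmo1 (4.15) and isg15 (3.70) were below the median of the foreign sequences. The mutant arrays spread widely for isg15 (5.41 ± 1.74), and its call ended without any of 6 arrays, at adjusted p-values from 0.0581 to 0.116, and when only the 48 hpf arrays entered the fit (0.12). The value of runx1 was -0.05 ± 0.13 (adjusted p = 0.84) at a level near background.

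The p53 response list shifted up by camera, but not with an estimated correlation. In that list 9 of 16 rose, 2 fell and 5 did not pass (9 and 2 adjusted over the list alone, camera adjusted p = 0.000166; adjusted p = 0.146 with an estimated correlation). Besides phlda3 and mdm2 they included bbc3 (1.48), rps27l (1.54), gadd45aa (1.48) and baxa (0.90), and those that fell were mdm4 (-0.50) and gadd45ab (-0.49). Of 16 apoptosis machinery genes 6 rose, 1 fell and 9 did not pass (6 and 1 adjusted over the list alone), among them casp8 (0.97), bada (1.02), bik (0.90) and apaf1 (0.53), while diabloa fell (-0.78). That list was not shifted by camera (adjusted p = 0.102) and moved by fry (adjusted p = 0.013). In the innate immune and interferon list 6 of 16 rose and 10 did not pass (6 adjusted over the list alone, camera adjusted p = 0.0772, fry adjusted p = 0.0368), with irf1b at 1.02, nfkb2 at 0.46 and irf1a at 0.31. Histone genes hist2h2l (1.33, with another probe set at 0.34 that was not called), h2ax (0.50) and histh1l1 (0.49) rose of 8 (3 adjusted over the list alone, camera adjusted p = 0.252, fry adjusted p = 0.00405).

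In the Myc network 6 of 9 fell, 1 rose and 2 did not pass (6 and 1 adjusted over the list alone), with mycn at -0.98, myclb at -0.80, mych at -0.88 and mxd4 at 0.67. In ribosome biogenesis 19 of 51 fell and 32 did not pass (30 lower and 1 higher adjusted over the list alone). Values were -0.76 for nop58, -0.91 for mybbp1a (another probe set at -0.27 was not called), -0.55 for bxdc2 and -0.68 for wdr43. In DNA replication 16 of 41 fell and 25 did not pass (27 adjusted over the list alone), with mcm5 at -0.91, the methylation maintenance factor uhrf1 at -1.02, pold2 at -0.95 and slbp at -0.89. Their camera adjusted p-values were 0.000171, 3.6e-11 and 4.6e-11, and adjusted p = 0.113, 0.309 and 0.321 with an estimated correlation. Of 38 mitosis genes 3 rose (kif20a at 1.64, with another probe set at 0.10 that was not called; prc1b at 0.58; kif23 at 0.36, with another probe set at -0.19 that was not called) and 2 fell (ndc80 at -0.65 and mad2l1 at -0.44). The mitosis list was not shifted (3 and 2 adjusted over the list alone, camera adjusted p = 0.882, test direction down and median just below 0 against a mean of 0.03). Against the stage-matched wild type reference its median was -0.15, with 2 members higher and 6 lower. Of 18 DNA repair and checkpoint kinase genes xrcc6 rose (0.39) and apex1 (-0.41), rad9a (-0.49) and unga (-0.51) fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.106). Of 6 cohesin loaders and regulators esco2 (-0.92) and pds5b (-0.57) fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.882, median 0.15 against a mean of -0.09). Ribosomal protein genes were called in 0 of 66 by limma, with 0 higher and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.74, median 0.01 against a mean just below 0).

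The erythroid and myeloid lists were lower. In the erythroid list 8 of 16 fell and 8 did not pass (8 adjusted over the list alone, camera adjusted p = 3.11e-05; adjusted p = 0.25 with an estimated correlation). They included cahz, the membrane protein gene epb41b (-1.70), the anion exchanger slc4a1a (-2.73) and alas2, the first enzyme of haem synthesis in red cells (-1.31). The median of the list was -0.46, and -0.16 against the stage-matched wild type reference. In the myeloid list 5 of 15 fell, 2 rose and 8 did not pass (5 and 2 adjusted over the list alone, camera adjusted p = 0.0381; adjusted p = 0.309 with an estimated correlation). Those that fell were lyz, the neutrophil peroxidase mpx (-0.91, while 2 other probe sets were not called and read 0.21 at most), mmp13a (-1.29), cebpa (-0.75) and spi1b (-0.29), and lcp1 (0.53) and cyba (0.43) rose. This list passed the threshold only with certain arrays and settings: its adjusted p was 0.0876 and 0.0613 without wild type replicates 1 and 4, 0.0706 and 0.0883 without mutant replicates 2 and 3, and 0.0684 with the mean of a gene's probe sets. Its median of -0.06 turned to 0.01 against the stage-matched reference. Of 11 blood stem and progenitor genes myb (-0.77) and runx3 (-0.51, with another probe set at -0.11 that was not called) fell and meis1b rose (0.34; 4 and 1 adjusted over the list alone, camera adjusted p = 0.273). Of 8 endothelium genes plvapb (-1.83), aplnra (-0.57) and the receptor gene kdrl (-0.87) fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.14, fry adjusted p = 0.00498).

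Lens genes fell most as a share: 8 of 11, with 3 not passing (8 adjusted over the list alone, camera adjusted p = 3.83e-09; adjusted p = 0.13 with an estimated correlation). They included the crystallins cryba4 (-2.15) and crygmxl2 (-1.90), the filament gene bfsp2 (-1.21) and prox1a (-0.87). The median of the list was -0.87, and -0.39 against the stage-matched reference. Of 20 neural progenitor genes 6 fell, 1 rose and 13 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.000575; adjusted p = 0.309 with an estimated correlation). Among them were ascl1b at -2.40, ascl1a at -1.91, fabp7a at -1.95, sox3 at -0.51 and, as the member that rose, her9 at 0.42. The 2 other probe sets of sox3 were not called, and the mean of its probe sets had an adjusted p of 0.0634. Of 27 differentiated neuron genes isl2a (-1.03), isl1a (-0.93, with another probe set at -0.31 that was not called), neurod1 (-1.0) and inab (-0.90) fell and gap43 rose (0.68; 5 and 1 adjusted over the list alone, camera adjusted p = 0.248, median 0.02 against a mean of -0.08). Of 19 photoreceptor genes neurod4 (-0.65), crx (-0.49) and nr2e3 (-0.28) fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.882, median 0.03 and mean just below 0). Of 7 protocadherins 4 fell and 3 did not pass (4 adjusted over the list alone, camera adjusted p = 0.0023; adjusted p = 0.143 with an estimated correlation). The 4 were pcdh10a (-1.45, another probe set at -0.09), pcdh19 (-1.12), pcdh18a (-0.83, another probe set at 0.10) and pcdh10b (-0.68).

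Skeletal muscle, heart and pharyngeal cartilage shifted down by camera. In skeletal muscle 4 of 33 fell, 1 rose and 28 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.00551; adjusted p = 0.617 with an estimated correlation and 0.27 by fry). Those that fell were mb, which encodes myoglobin (-1.15), tmod4 (-0.67), myod1 (-0.56) and acta1a (-0.63), and tnni2b.1 rose (1.16), in arrays whose actin 3' to 5' difference was higher by 0.949. Against the stage-matched wild type reference the direction of this list turned, from a median of -0.32 to 0.25, with 4 members higher and 4 lower. In heart 4 of 14 fell and 10 did not pass (4 adjusted over the list alone, camera adjusted p = 0.00997; adjusted p = 0.25 with an estimated correlation): klf2a (-1.75), tnnc1a (-0.82), hand2 (-0.78) and myh7 (-0.47). In pharyngeal cartilage 4 of 19 fell and 15 did not pass (4 adjusted over the list alone, camera adjusted p = 0.00282; adjusted p = 0.151 with an estimated correlation): tbx1 (-0.67), dlx5a (-0.44), barx1 (-0.42) and runx2a (-0.67, with another probe set at 0.05).

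The other lists were not shifted at 48 hpf. In epidermis 6 of 24 rose, 4 fell and 14 did not pass (7 and 4 adjusted over the list alone, camera adjusted p = 0.882). Those that rose included krt1-19d (1.28) and cldne (0.65), and those that fell were krt15 (-1.52), agr2 (-1.46), krt5 (-0.57) and krt94 (-0.45). In pancreas and gut 5 of 26 fell, 2 rose and 19 did not pass (5 and 2 adjusted over the list alone, camera adjusted p = 0.14). The carboxypeptidase cpa5 was at -1.54, ins at -0.69, foxa3 at -0.72, ptf1a at -0.71 and gcga at -0.52, and cpa4 was at 0.39 and fabp2 at 0.55. Of 24 liver and yolk genes apoea (-1.66) and hpxa (-0.65) fell and fetub rose (0.53; 2 and 1 adjusted over the list alone, camera adjusted p = 0.882, median 0.01 against a mean of -0.06). Of 15 neural crest and pigment genes sox9b (-1.75, with another probe set at -0.09), gch2 (-1.01) and foxd3 (-0.52) fell, and crestin (0.69) and the melanosome gene pmelb (0.59) rose (4 and 2 adjusted over the list alone, camera adjusted p = 0.288). Of 13 somite clock and tailbud genes cyp26a1, which clears retinoic acid (-2.47), evx1 (-0.86) and fgf8a (-0.60) fell (3 adjusted over the list alone, camera adjusted p = 0.143). Of 8 notochord and hatching gland genes cd63 rose (0.46; 1 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.961). Of 17 hypoxia response genes vegfaa (-0.56), epas1a (-0.63, with another probe set at -0.29) and igfbp1a (-1.90) fell, and hk2 (0.42) and igfbp1b (0.46) rose (3 and 2 adjusted over the list alone, camera adjusted p = 0.581). Of 28 heat shock and stress genes hspb1 rose (1.08) and chac1 (-1.49, with another probe set at 0.03) and hsp70.3 (-2.0) fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.549). Of 42 Hox genes hoxd10a (0.53), hoxd4a (0.39, with another probe set at 0.28) and hoxa11b (0.45) rose and hoxb8a fell (-0.58, with another probe set at -0.15; 3 and 1 adjusted over the list alone, camera adjusted p = 0.811).

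The share of higher calls at 48 hpf was 56.3%, but 45.7% after cyclic loess and 49.2% with arrays centred on their medians, so the balance of the directions depended on the scaling. The number of shifted lists, 12, was reached in 6 of the 35 splits of the 8 arrays. The calls of apex1, barx1, crx, dlx5a, fetub, hoxa11b, histh1l1, irf1a, kif23, meis1b, myh7, nfkb2, nr2e3, pmelb, rad9a, runx2a, unga and xrcc6 each ended without any of 3 to 8 arrays, at adjusted p-values from 0.0507 to 0.117. Those of pds5b (adjusted p = 0.0609 and 0.0615) and neurod4 (0.0619 and 0.0631) ended without wild type replicates 1 and 2, and that of hoxb8a without wild type replicate 1 (0.0571) or mutant replicate 4 (0.0528).

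**Figure D2:**
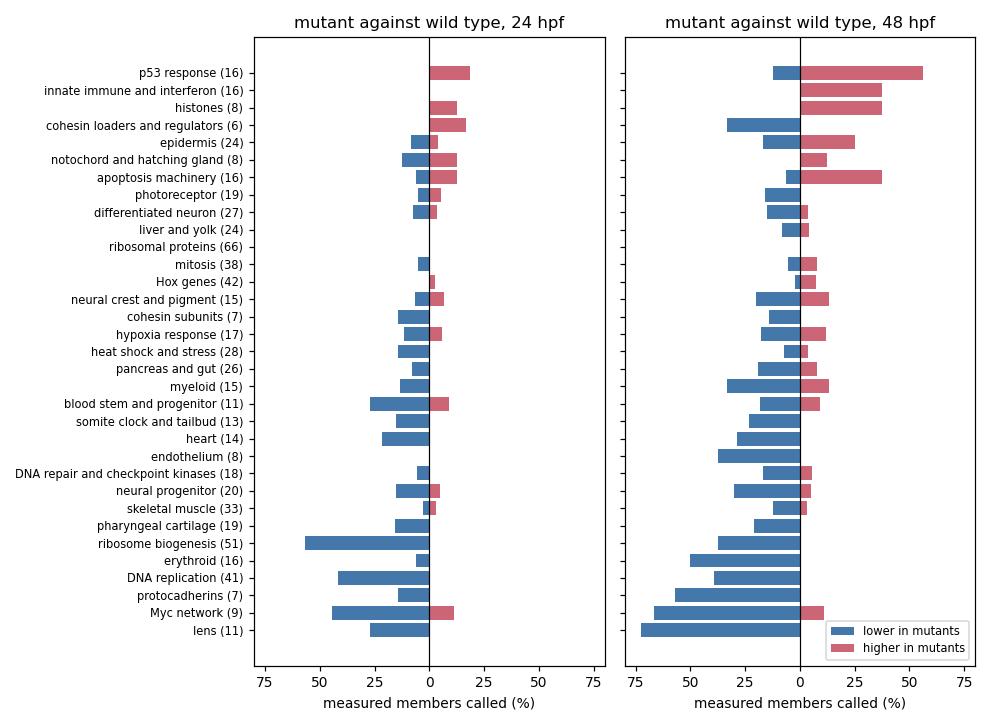
Share of the measured members of each gene list called lower (blue, to the left) or higher (red, to the right) in mutants at 24 hpf and 48 hpf, with the number of measured members in parentheses and lists ordered by their median log2 change at 48 hpf. The largest share at 24 hpf is that of ribosome biogenesis (29 of 51 lower). At 48 hpf lens (8 of 11), Myc network (6 of 9) and protocadherins (4 of 7) have the largest shares lower, and p53 response (9 of 16) the largest share higher.

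The genotype effects at the times were then compared with each other, since no array is shared between them. Of the 505 probe sets higher at 24 hpf 249 were also among the 1358 higher at 48 hpf, against 44.2 for independent calls (Fisher's exact test, p = 1.37e-131). Of the 634 lower at 24 hpf 329 were among the 1055 lower at 48 hpf, against 43.1 (Fisher's exact test, p = 1.55e-225), and 8 were called in opposite directions. Fisher's test counts probe sets as independent, and both comparisons share a single estimate of the spread, so that these p-values overstate the evidence. Genes low at both times included gja1b, inka1a, myca, ascl1a and ascl1b, and genes high at both times included hnmt, tp53inp1 and rps27l. Across the 15502 probe sets, which are not independent replicates, the log2 changes had a Pearson r of 0.584 and a Spearman rho of 0.498.

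**Figure D3:**
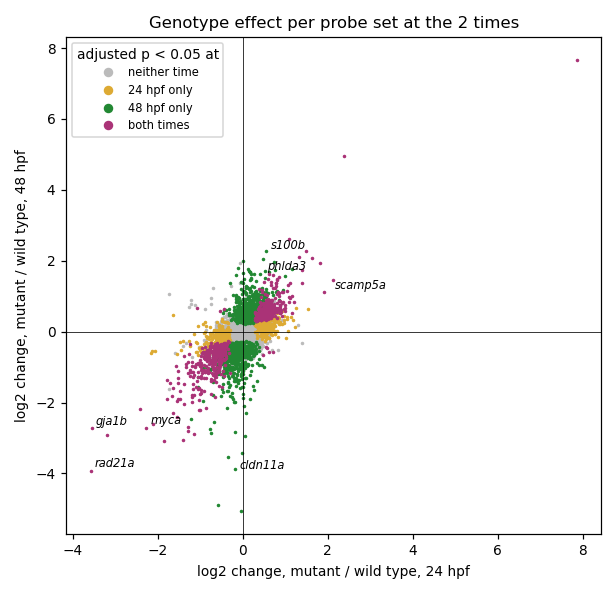
Log2 change, mutant over wild type, of each probe set at 24 hpf (horizontal) and 48 hpf (vertical), coloured by the times at which the adjusted p was under 0.05. Probe sets called at both times lie mostly in the lower left and upper right, with rad21a at -3.58 and -3.92, while cldn11a (-0.19 and -3.86) changed at 48 hpf.

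The interaction tested whether the genotype effect differed between 24 and 48 hpf. The genotype effect on the p53 targets mdm2 and phlda3 was more positive at 48 hpf, with differences of 1.65 ± 0.22 (adjusted p = 0.00106) and 1.57 ± 0.23 (adjusted p = 0.0019), and the differences of s100b (1.74 ± 0.30) and atp1a1a.2 (1.52 ± 0.32) were positive as well. The sterol synthesis genes hmgcs1 (1.74 ± 0.41) and cyp51 (1.43 ± 0.22) also had positive differences, although the 3 other probe sets of cyp51 were not called and read -0.03, -0.11 and -0.29. The differences were negative for cldn11a (-3.67 ± 0.16, adjusted p = 2.06e-10), and2 (-3.18 ± 0.49), and3 (-2.62 ± 0.27), the homeobox gene gsc (-2.38 ± 0.19), the chemokine ccl25b (-2.08 ± 0.21) and apoea (-1.92 ± 0.36). In all, 225 probe sets were called, 94 with a positive and 131 with a negative difference.

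By list, the genotype effect was more positive at 48 hpf for p53 response (4 of 16 members with a positive difference, mdm2, phlda3, baxa at 1.03 and bbc3 at 0.88; 7 up and 1 down adjusted over the list alone, camera adjusted p = 0.00249; adjusted p = 0.548 with an estimated correlation). It was more negative for erythroid (3 of 16 members with a negative difference, cahz at -1.64, alas2 at -1.38 and epb41b at -1.23; 5 adjusted over the list alone, camera adjusted p = 0.00107; adjusted p = 0.722 with an estimated correlation) and lens (3 of 11, crygmxl2 at -1.66, bfsp2 at -1.38 and cryba4 at -1.27; 5 adjusted over the list alone, camera adjusted p = 3.52e-09; adjusted p = 0.219 with an estimated correlation). It was also more negative for neural progenitor (1 of 20, ascl1b at -0.84; 1 adjusted over the list alone, camera adjusted p = 0.0285; adjusted p = 0.722 with an estimated correlation) and differentiated neuron (1 of 27, isl1a at -1.05, with another probe set at -0.43 that was not called; 1 adjusted over the list alone, camera adjusted p = 0.0472; adjusted p = 0.864 with an estimated correlation). The count of probe sets was 144 without wild type replicate 3 at 24 hpf, 125 without mutant replicate 3 at 24 hpf and 125 without wild type replicate 1 at 48 hpf. The call of hmgcs1 ended without any of 13 arrays and with cyclic loess (adjusted p of 0.0502 to 0.0915), that of atp1a1a.2 without any of 5 arrays (0.0531 to 0.0579), that of cahz without any of 13 (0.0502 to 0.0767), and that of cyp51 with the mean of its probe sets (0.467).

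Wild type embryos changed strongly between 24 and 48 hpf, which gives the scale of normal development. Muscle and fin fold genes were among the largest rises. The gene tcnbb, a vitamin B12 carrier protein, was 80.6-fold higher at 48 hpf (log2 change 6.33 ± 0.42), the mitochondrial ADP/ATP carrier slc25a4 71.7-fold (6.16 ± 0.24), the muscle parvalbumin pvalb1 66.4-fold (6.05 ± 0.55), and2 42.6-fold (5.41 ± 0.34), the troponin tnnt3b 38.0-fold (5.25 ± 0.49) and and1 37.1-fold (5.21 ± 0.33). The falls were led by the presomitic mesoderm factor msgn1 (-3.93 ± 0.44), the urate oxidase uox (-3.90 ± 0.43), the tailbud homeobox gene cdx4 (-3.43 ± 0.24), ctsc (-3.05 ± 0.15), efemp2b (-2.82 ± 0.24) and wdr90 (-2.78 ± 0.15). There were 4696 called probe sets, 1957 higher and 2739 lower. The share of higher calls was 41.7%, but 54.2% after cyclic loess.

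Of the 33 lists 15 shifted with time in wild types by camera. None was called with an estimated correlation, where the 15 lists had adjusted p-values of 0.102 to 0.486 and 6 of all 33 lists had an unadjusted p under 0.05. Falling lists were ribosome biogenesis (46 of 51 fell; 47 adjusted over the list alone), DNA replication (38 of 41; 41 adjusted over the list alone), mitosis (26 of 38; 32 adjusted over the list alone), DNA repair and checkpoint kinases (13 of 18; 15 adjusted over the list alone), somite clock and tailbud (9 of 13; 10 adjusted over the list alone) and ribosomal proteins (9 of 66; 0 adjusted over the list alone). Rising lists included skeletal muscle (23 of 33; 23 adjusted over the list alone), differentiated neuron (21 of 27; 23 adjusted over the list alone), lens (7 of 11; 9 adjusted over the list alone), with crygmxl2 at 4.99 and cryba4 at 5.08, and myeloid (6 of 15; 6 adjusted over the list alone), with lyz at 4.29.

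The mutants went through much of the same change. Their largest rises were in pvalb1 (6.18 ± 0.55), tnnt3b (5.32 ± 0.49), slc25a4 (5.09 ± 0.24), tnni2a.4 (4.71 ± 0.52), tcnbb (4.64 ± 0.42) and pvalb4 (4.48 ± 0.30). Their largest falls were in uox (-3.50 ± 0.43), msgn1 (-3.35 ± 0.44), the keratin krt99 (-3.13 ± 0.38), cdx4 (-3.08 ± 0.24), the myogenic factor myog (-2.34 ± 0.15) and efemp2b (-2.31 ± 0.24). Of 3668 called probe sets 1708 were higher and 1960 lower at 48 hpf. The share of higher calls was 46.6%, but 54.3% after cyclic loess and 39.8% with arrays centred on their medians, so the direction of the majority turned with the scaling. Probe sets called in both genotypes numbered 2485, of which 2468 moved in the same direction. Another 2211 were called in wild types and not in mutants and 1183 in mutants and not in wild types, without a test of that difference beyond the interaction. Across probe sets, which are not independent replicates, the time changes had an r of 0.816 and a least-squares slope of 0.697, mutant on wild type. By camera 19 lists shifted, 0 of them with an estimated correlation (adjusted p from 0.134 to 0.437 for the 19, and 7 of 33 lists with an unadjusted p under 0.05). Among them were p53 response (7 of 16 rose and 3 fell; 8 and 4 adjusted over the list alone), with phlda3 at 1.59 and mdm2 at 1.18 and falls of btg2 (-0.55), mdm4 (-0.39) and xpc (-0.31), lens (crybb1 at 4.45, cryba4 at 3.81 and crygmxl2 at 3.32 rose of 11 and prox1a fell, at -0.37; 3 and 1 adjusted over the list alone), and innate immune and interferon (7 of 16 rose; 8 adjusted over the list alone), with irf1b at 0.99.

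The stage index asked how far along the wild type time axis each array lay. At 24 hpf mutants were at -0.0201 ± 0.128 and wild types at 0.0212 ± 0.0915 (SD, n = 4), a difference of -0.0413 (exact two-sided permutation p = 0.629, adjusted p = 0.629) whose sign turned with an axis without a fold threshold (0.0021). At 48 hpf mutants were at 0.691 ± 0.119 and wild types at 0.975 ± 0.0160, a difference of -0.284 (exact two-sided permutation p = 0.0286, the smallest possible), which did not pass after adjustment over the 2 times (adjusted p = 0.0571). Without any of the 4 wild type arrays at 48 hpf the difference was -0.296 to -0.27 (exact permutation p = 0.0571 each). All 4 mutant arrays, from 0.581 to 0.857, lay below all 4 wild type arrays, from 0.956 to 0.995. Of the 2413 probe sets called between genotypes at 48 hpf, 928 differed against the direction of the wild type time change, 261 along it and 1224 were not called for time in wild types. The genotype difference and the wild type time change share the wild type arrays at 48 hpf, which alone pushes such counts against the time change. A lower index can come from a delay or from genotype changes in the genes of the axis, and the index cannot tell these apart.

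**Figure D4:**
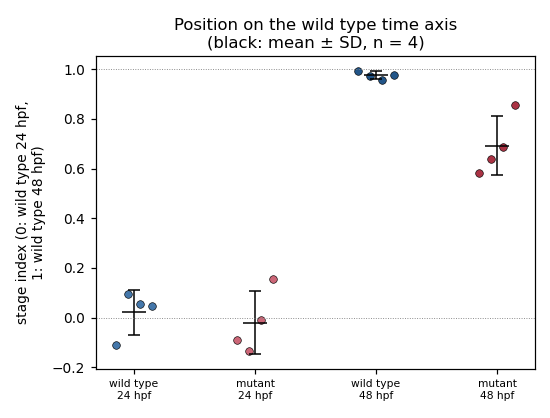
Stage index of each array (points) with the group mean and SD (black, n = 4), where 0 is the wild type mean at 24 hpf and 1 that at 48 hpf. Mutants at 48 hpf lie between 0.581 and 0.857 and wild types between 0.956 and 0.995.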

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

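Of the tests in this part, those of slower development for the pattern as a whole and for ribosome biogenesis and DNA replication genes, of the 3 arrays that stand apart, of a lower share of dividing cells, both on the actin control, the permutation of list means and the comparison of replication with mitosis genes against the stage-matched reference were chosen only after the result was seen.

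A gap test for a single array far from its group was applied to 48 groups of 4 arrays and found 4 arrays, where chance finds about 1 in 20 groups. Wild type replicate 1 at 24 hpf had a mean correlation of 0.9847 with its group and wild type replicate 3 at 48 hpf one of 0.9855. Mutant replicate 1 at 48 hpf had a 3' minus 5' log2 difference of 4.077 for acta1, and mutant replicate 4 at 24 hpf a log2 intensity of 5.484 for aqp1a.1. The genotype effect differed between the times by a log2 of 1.744 for hmgcs1, 1.738 for s100b, 1.647 for mdm2, 1.568 for phlda3, 1.516 for atp1a1a.2 and 1.429 for cyp51. The difference was -3.674 for cldn11a, -3.178 for and2, -2.624 for and3, -2.375 for gsc, -2.08 for ccl25b and -1.915 for apoea. The control probe sets of acta1, outside the main comparisons, differed in 3' minus 5' log2 value by 0.6163 at 24 hpf and 0.9487 at 48 hpf, mutant minus wild type.

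For the comparisons of 2 groups, chance as the source of the counts of probe sets is argued against by other splits of the arrays. With 35 splits the real one cannot stand out by more than 1 in 35. At 24 hpf 1 of 35 splits, the real one, gave 1139 probe sets and the highest other gave 93. At 48 hpf 1 of 35 gave 2413, the highest other 7. For time, 1 of 35 splits gave 4696 in wild types and 1 of 35 gave 3668 in mutants, with 1 as the highest other in each. For the interaction 3 of 100 drawn relabellings, the real one included, gave at least 225 probe sets, with 1017 as the highest other. The 2 larger draws, 1017 and 572, kept the real labels at 48 hpf or turned them all, so that they still carry the genotype effect. Most draws break the genotype effect itself, so that they cannot test the interaction apart from it, and chance was not excluded there. Chance was not excluded for the numbers of shifted lists. At 24 hpf 17 of 35 splits gave at least the real 6 lists, the highest other 13, and at 48 hpf 6 of 35 gave at least the real 12, the highest other 15. In exact two-sided permutation tests of list means, 10 of 33 lists at 24 hpf and 19 of 33 at 48 hpf reached the smallest possible p of 0.0286 (lowest adjusted p = 0.0943 and 0.0496).

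The mutant values at 48 hpf ran against the wild type change from 24 to 48 hpf: with the wild type arrays at 48 hpf split between the comparisons, r across probe sets, which are not independent replicates, was -0.2518 at most and -0.322 at least, against -0.366 with shared arrays, where simulated unchanged groups gave -0.497 (covariance -0.0729 observed and -0.0116 simulated). Slower development may account for part of the pattern, as a hypothesis. It is argued against for ribosome biogenesis and DNA replication genes, whose lists fall with time in wild types and had medians below 0 in mutants (higher median -0.4229). In mutants 19 of 51 and 16 of 41 were called lower. With an estimated correlation camera called neither list, in mutants at 48 hpf (adjusted p = 0.309 and 0.321) or over time in wild types (adjusted p = 0.224 and 0.286). Slower development as the source of all changes was tested against the stage-matched wild type reference. There 83.05% of the calls (2004 of 2413) remained in the same direction. This held for 96.4% of the 1224 without a time call in wild types, which that reference can hardly alter. Of the 928 that ran against the time change it held for 60.7%. Against that reference 3145 probe sets were called in all. The reference draws on wild type arrays of both times, so that its contrast has a smaller standard error by construction, which makes calls easier. The reference lies on a straight line between 24 and 48 hpf. A delay could therefore leave calls in genes that change early, late or only between these times. The share that remained argues against a delay only where genes change evenly. List medians moved from -0.32 to 0.25 in skeletal muscle, from -0.46 to -0.16 in erythroid (8 members lower before and 7 after) and from -0.87 to -0.39 in lens (8 and 6), but little in neural progenitor (-0.20 to -0.22), heart (-0.14 to -0.11), pharyngeal cartilage (-0.32 to -0.26) and protocadherins (-0.68 to -0.67), and a delay larger in a single tissue was not tested. The median of the differentiated neuron list moved from 0.02 to 0.37, with 8 members higher and 4 lower against that reference. Its median time change was 0.91 in wild types and 1.02 in mutants, so that this median showed no lag. The 3 arrays that stand apart are argued against as the source of the stage difference. The arrays left without them still lay apart, mutants at 0.581 to 0.688 and wild types at 0.972 to 0.995. Yet the difference with the axis unchanged (-0.3461) could only widen, because both 48 hpf arrays left out lie toward the other genotype.

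At 48 hpf 16 of 41 DNA replication genes fell, while the mitosis list was not shifted. The DNA replication list shifted down by camera (adjusted p = 4.6e-11), but not with an estimated correlation (adjusted p = 0.321). That a lower share of dividing cells would lower both lists alike was assumed and not tested. In wild types their medians fell unequally with time (-0.72 for DNA replication, -0.50 for mitosis). The medians of the genotype change at 48 hpf differed by -0.4576, outside the -0.255 to 0.247 that covered 95% of 10000 relabelled lists. Relabelling treats genes as independent, although their estimated correlation was 0.613 in DNA replication and 0.34 in mitosis, so that this range is too narrow. The difference of array means had an exact permutation p of 0.0286. A lower share of dividing cells is argued against only under the assumption of equal falls. Mitosis genes fall with time in wild types, so that a delay could mask a fall. Against the stage-matched reference their median was -0.15, with 2 higher and 6 lower, still apart from replication genes by -0.54. Relabelled lists gave -0.251 to 0.252 there, with the same limit and without a test on arrays. Under cyclic loess the difference was still -0.4547, so that this rescaling of already normalized values did not remove it. Median centring moves all genes of an array alike and cannot change the difference. Other normalizations were not tested. A change in replication genes tied to the genotype may remain as a hypothesis, and a change in the mix of cycling cells was not tested.

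The acta1 control probe sets had a higher 3' to 5' difference in mutants. Degraded or less fully labelled RNA throughout the pools would move the GAPDH control too, if both controls respond alike. The GAPDH difference was 0.124 at 24 hpf and 0.0193 at 48 hpf, against 0.616 and 0.949 for acta1. These values argue against such RNA only under that condition. In wild types at 24 hpf the 3' minus 5' value was 3.07 for acta1 and 0.41 for GAPDH. A lower level of muscle actin RNA with unequal probe response could also give the higher acta1 difference. It cannot be told apart from a change in the RNA itself. Mutant minus wild type, the 3' probe set of acta1 read -0.2175 at 24 hpf (exact permutation p = 0.686). At 48 hpf it read -0.37 (exact permutation p = 0.0286).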

How the results depend on the processing

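The alternative that leaves out 3 arrays together and, for the stage index, the wild type arrays left out in turn were chosen only after the data were seen. Of 5397 values for 399 gene comparisons, 4959 kept their direction and side of the threshold, 434 lost a call, 4 gained one (smc1al under 3 alternatives, smc3 under 1) and 0 reversed. Only genes called in the main fit entered, besides the cohesin subunits, myca, mdm2 and runx1, so that few calls could be gained. A change of sign without a call before or after was counted as kept. Array weights raised the count at 24 hpf to 2908 and that of the interaction to 530. An adjusted p under 0.01 left 417, 1263, 71, 2984 and 2048 probe sets (24 hpf, 48 hpf, interaction, time in wild types, time in mutants), and a change of at least 2-fold left 117, 341, 112, 786 and 573, by construction fewer. Camera with an estimated correlation called 0 lists at both times, against 6 and 12 (unadjusted p under 0.05 for 5 and 6 lists), and fry called 8 and 18. Without the 3 arrays least like their groups there were 1889 probe sets and 10 lists at 24 hpf. With the axis also built again without them, the stage difference at 48 hpf was -0.3685 (exact permutation p = 0.1, the smallest 3 against 3 arrays can give). With the axis unchanged it was -0.3461. The stage difference at 24 hpf turned to 0.0021 with an axis without a fold threshold. The cause was not tested, except where the construction gives it.

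With 1 array left out, the counts ranged from 646 to 1376 at 24 hpf, 1835 to 2762 at 48 hpf, 125 to 231 for the interaction, 4112 to 4958 for time in wild types and 2616 to 4050 for time in mutants, and the lists from 6 to 11 and 11 to 15. The correlation of the effects at the times ranged from 0.549 to 0.623, and the stage difference from -0.0998 to -0.0025 at 24 hpf and -0.34 to -0.248 at 48 hpf. Other counts stayed within 1.5 times of those reported. Background correction and scan date or slide as a block were not run.

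Replicate numbers were not taken to pair the samples, since replicate 2 fell short of a correlation of 0.1 in most pairs of groups, but the values leave partial sharing open. Deviations of arrays with the same number correlated by 0.4255, -0.307, 0.3049 and 0.3924 between genotypes at 24 hpf, by 0.0247 to 0.3879 between wild types at 24 hpf and mutants at 48 hpf and by 0.0436 to 0.3986 between mutants at both times, with 3 of 4 arrays best with their own number in each. Pairs with wild types at 48 hpf lay between -0.2403 and 0.1553, with 0 or 1 of 4 best. A fit with the replicate block gave 1360, 2691, 286, 5005 and 3912 probe sets and 8 and 12 lists. The stage difference at 48 hpf stayed at -0.2844 with the replicate block, where a test on 4 pairs cannot pass (exact permutation p = 0.125). Signal near the level of the foreign sequences limits fold changes of dim genes.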

Other observations

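The tests on sterol synthesis genes and on the neighbours of rad21a, and the comparison of actinodin levels with wild types at 24 hpf, were chosen only after the result was seen. Both the sterol synthesis and the actinodin genes were also put together as lists after the data were seen.

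Sterol synthesis genes rose together at 48 hpf. Of 10 measured members, msmo1 (1.98), hmgcs1 (1.58) and cyp51 (1.39) were among the 25 largest named increases, and the 7 others rose as well, among them fdps (0.91), fdft1 (0.91), insig1, which restrains the pathway (0.76), and dhcr7, which makes a late step of cholesterol synthesis (0.42). The value of cyp51 came from a single probe set, and its other probe sets were not called for the interaction. None of the 10 passed at 24 hpf by limma, where acat2 was closest (0.34, adjusted p = 0.0517). A shared rise of the pathway may extend beyond the genes that drew attention to it, as a hypothesis: without those 3 members camera gave p = 1.63e-05 for the rest (median 0.61; p = 0.0192 with an estimated correlation).

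The fin fold actinodins and1 (-1.96), and2 (-3.53) and and3 (-2.82) all fell at 48 hpf, whereas 0 of 3 passed at 24 hpf by limma, with and1 at -0.93 (adjusted p = 0.106). Slower development of the fin fold cannot be told apart from a change tied to the genotype. Against the stage-matched wild type reference the median was -1.427, with and1 at -0.40 (adjusted p = 0.391), and2 at -1.92 and and3 at -1.43. A median well below 0 had been set before this test to count against a delay. That reference sits at the mean stage index of the mutants, however, and cannot test a delay larger in the fin fold. The mutant levels at 48 hpf lay above those of wild types at 24 hpf, by a log2 of 3.26 for and1, 1.88 for and2 and 1.85 for and3, between the wild type levels at both times.

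Genes that neighbour rad21a on its chromosome were called about as often as genes on other chromosomes, with odds ratios of 1.2201 (95% interval 0.644 to 2.14) at 24 hpf and 1.18 (0.749 to 1.81) at 48 hpf over 137 neighbours. Local effects carried with the mutant haplotype could still be present, because the intervals do not exclude a moderate excess. The 137 neighbours also spanned a wide stretch on both sides of rad21a, so that effects confined to the closest genes would be diluted.

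Some of the largest changes were in probe sets without a gene symbol, chosen after their values were seen. The probe set with the largest rise was higher in mutants by a log2 of 7.86 at 24 hpf and 7.67 at 48 hpf (limma adjusted p = 3.34e-12 and 1.69e-12), from wild type means of 4.32 and 4.70 near the median of the foreign sequences (4.66). The most negative change at 48 hpf was -5.06 (limma adjusted p = 2.68e-14), from 8.94 to a mutant mean of 3.88, below that median. Values at background compress both differences.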
